A study of Mus musculus with 18 samples.

How the data were processed

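RNA was sequenced from 3 dendritic cell subsets sorted from mouse spleen: the conventional subsets cDC1 and cDC2, and plasmacytoid dendritic cells (pDC). Per the labels, each subset was taken from mice with a floxed Hdac1 gene and from mice that also carried the Mx1-Cre recombinase, all given polyI:C 2 weeks before sorting, which gives 6 groups of 3 samples. The submitters' processing notes name kallisto, DESeq2 and GRCm38, without their roles or versions.

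The authors deposited 6 tables, a raw and a normalized table for each subset, with 36 value columns under 18 different column names. The column names were compared with every title, description and other label of the 18 samples, and 0 of the 36 columns could be matched to a sample. All 36 columns were left unused in every result. A match by column order or by accession order would have rested on an assumption about order. A match by the values themselves would have assumed the genotypes that the comparison is about. In numeric order, the column names fell to the subsets in the same sequence as the samples in accession order. The column names themselves give no genotype. Pairing them with the samples in this sequence would give each column one, but only by assuming the order, so the sequence was not used. While the format of the raw tables was inspected, the counts of Hdac1 and Hdac2 were also seen. They were not used to assign any column. The planned tests between genotypes, between subsets and over gene lists all needed the genotype of each column and were therefore not run. No expression value, depth per sample, fold change or p-value is given, and no named-gene rule was applied.

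Levels by subset and depth per column would need only the subset in a table's name, but they were not computed. What was computed was which gene symbols the tables list. Only the gene column of each table was read for this. Symbols were compared with those of GENCODE M21, an annotation of GRCm38, and with 36 lists of genes that were written before the data were examined. The lists cover histone deacetylases and their complexes, dendritic cell identity and development, antigen presentation, maturation, cytokines, interferon-stimulated genes, cell cycle, apoptosis, chromatin, metabolism, RNA quality and markers of other cell types. Some lists give an older and a newer symbol of one gene, and their counts are of symbols, not of distinct genes. Each table is taken to concern the subset in its name. The rule by which genes entered a table is not given in the sources used here, so a listed gene is not thereby an expressed one, and a symbol that was not found was not analysed here.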

Results

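The series measured RNA from sorted splenic dendritic cells of mice in which Hdac1, a class I histone deacetylase, was floxed or was floxed in the presence of Mx1-Cre, a recombinase induced through interferon signalling. It asked how the loss of Hdac1 changes transcription in cDC1, cDC2 and pDC. The labels give 6 groups, a control and a knockout group for each subset, with 3 samples in each and 18 in all. The spleens were taken 2 weeks after polyI:C. The sort gates in the labels separated cDC1 by XCR1, cDC2 by CD11b and pDC by BST2.

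The comparison of knockout with control was not made in any subset. The 36 value columns of the 6 tables carry codes, and 0 of them could be matched to a sample label. It is therefore not known from the labels which columns came from knockout mice. The level of Hdac1 in each sample, the number of changed genes in each subset and the difference between subsets are not reported.

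The gene symbols in the tables could be compared without the value columns. There were 17017 genes listed for cDC1, 16306 for cDC2 and 16277 for pDC. In each subset all genes of the raw table were also listed in the normalized table. All 3 subsets shared 15219 of the 17903 genes listed in at least 1 of them. The genes listed for a single subset numbered 695 for cDC1, 271 for cDC2 and 459 for pDC. Symbols of GENCODE M21 made up 97.1% of the list for cDC1, 97.1% for cDC2 and 97.2% for pDC. These are counts of table rows, with no replicates and no test. Of the 36 gene lists, 19 had the same members listed in all subsets and 17 did not. The 19 include the list of mitochondrially encoded genes, of whose 15 symbols 0 were found in any subset.

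Hdac1 was listed in the tables of all 3 subsets. In GENCODE M21 on GRCm38 the gene lies on chromosome 4, from 129516104 to 129542713 on the minus strand. All 11 classical histone deacetylases were listed in every subset. So were all 28 subunits on the list of HDAC1/2 corepressor complexes, which include the SIN3, NuRD and CoREST complexes.

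The lists of dendritic cell identity genes were almost fully represented for each subset. Many other lists were too, among them the erythroid and B cell markers, so this does not tell the subsets apart. For cDC1 identity, 23 of 26 symbols were listed in all subsets. Of the remainder, Sept3 is an older symbol of Septin3, which was listed in every subset. Cxx1a was not found in any subset. Fzd1, a Wnt receptor, was listed for cDC1 and cDC2 but was not found for pDC. All 29 cDC2 identity genes were listed in every subset. For pDC identity, 33 of 35 symbols were listed in all subsets. Dntt, which encodes terminal deoxynucleotidyl transferase, was listed for cDC2 and pDC but was not found for cDC1. D13Ertd608e was not found in any subset. All 45 transcription factors and cytokine receptors of dendritic cell development were listed in every subset.

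For MHC class II presentation 18 of 20 symbols, for MHC class I presentation all 25 and for interferon-stimulated genes 41 of 42 were listed, and these were the same symbols in every subset. Of the symbols not found, March1 and Rigi are other symbols of Marchf1 and Ddx58, which were listed in every subset. Ifi30 was not found in any subset. For maturation and migration, 26 of 29 genes were listed in all subsets. The chemokine gene Ccl17 and the costimulatory ligand genes Cd70 and Tnfsf4 were listed for cDC1 and cDC2 but were not found for pDC. Among cytokines and chemokines, Ifnb1, which encodes interferon beta, was listed for pDC alone, Ccl12 was listed for cDC2 alone, and Il10 and Il27 were listed for both conventional subsets but were not found for pDC. Of the pattern recognition genes, Tlr8 and Clec4d were listed for cDC1 and cDC2 but were not found for pDC.

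Markers of other cell types were listed in every table. All 16 erythroid markers were listed in each subset. Of the 20 B cell symbols, 19 were listed in every subset, and the other, Faim3, is an older symbol of Fcmr, which was listed. Of the 20 T cell symbols, 18 were listed in every subset, and Trac and Trbc1 were not found. Of the basophil and mast cell markers, 10 of 12 were listed for cDC1, 6 for cDC2 and 4 for pDC. Mcpt8, a basophil protease gene, Fcer1a, a subunit gene of the IgE receptor, and Prss34 were listed for cDC1 alone. Hdc, Cd200r3 and Cma1 were listed in every subset, Il4 for cDC1 and pDC, and Cpa3, Gata2 and Ms4a2 for cDC1 and cDC2. The list for cDC1 was also the longest over all genes, by a smaller margin. Of the 17903 genes listed in at least 1 subset, it held 17017, against 16306 for cDC2 and 16277 for pDC. The levels of these genes were not analysed here. None of the 15 mitochondrially encoded symbols was found in any table, and other spellings of them were not looked for. The share of mitochondrial RNA, a sign of RNA quality, was not analysed here, because no value column was used.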

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

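All alternatives given here were chosen after seeing the data. The count of columns matched to a sample label was 0 of 36 when a column's name had to be a word of a label, when it could lie anywhere inside a label, and when only its number was compared. The number of genes listed in all subsets was 15219 from the raw tables, from the normalized tables and with letter case ignored. It was 14807 when only symbols of GENCODE M21 were kept. Every gene of a raw table was also in its normalized table, so the normalized tables could not give a smaller number. The alternatives planned before the data were examined concern tests of expression. None of them was run, because no column name could be matched to a sample label. No paired analysis was possible because the columns carry no replicate number or group. The sample titles do give both, but no column was matched to a title. Control and knockout samples also came from different mice, so a shared replicate number would not in itself make them a pair. How depth limits the measurements was not analysed here.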
